A study of Mus musculus with 6 samples.

How the data were processed

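Total RNA of mouse liver was measured on 6 one-colour arrays, whose probe names are those of an Affymetrix mouse array of 12488 probe sets, 66 of them controls. Per the labels, 3 genotypes (wild type, Clock mutant and Cry-deficient, 1 of whose 2 arrays was described as a Cry1 and Cry2 double knockout) were sampled at 2 circadian times, with 1 array per group, in male mice 8 to 10 weeks old. A strain background was stated only for wild type. The allele of the Clock mutant, whether RNA of several mice was pooled, and the order of hybridisation are not given in the sources used here.

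The authors deposited 1 intensity per probe set and array. The deposited intensities are whole numbers, positive and negative, which does not arise without subtraction of a background or mismatch signal, and their mean differed between arrays, both read from the values themselves. The software, the kind of subtraction and any other step are not given in the sources used here. All 6 arrays were assigned to their groups by their titles.

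Each array was divided by the median ratio of its values to the geometric mean of the 6 arrays, over 6065 probe sets at or above the median by mean value and positive on every array. The log2 offsets were 0.12 and 0.15 in wild type at CT02 and CT14, -0.43 and 0.07 in the Clock mutant, and 0.00 and 0.20 in the Cry-deficient arrays, the fifth rounded from slightly below 0. Scaled values below the pooled median (606 scaled units) were set to that floor before log2 was taken, so a fold against a value at the floor is a lower bound, printed as "at least", and no fold is given where both values were at the floor. The signal above background, not the number of probes, limits what can be read of dim genes: between 4.75% and 8.05% of the kept genes were at the floor on an array.

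Probe sets were named from the platform's annotation table, with symbols looked up by gene number in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the probe sets, 10855 had 1 gene symbol, 396 had several and 1237 had none, and 10839 matched the RefSeq table by gene number, with 0 symbols updated. Those with several symbols or none were not used, nor were control probes. A gene was represented by its brightest probe set, which gave 8251 genes, of which 6178 had 1 probe set. Genes with a mean over the 6 arrays of at least the floor were kept (4844).

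For each genotype CT14 was compared with CT02, and each mutant with wild type at each time, 7 comparisons in all. With 1 array per group there is no replicate error within a group. An additive fit of genotype and time, with time as a block, leaves residual degrees of freedom but was not used to test genes. It takes the difference of the time effect between genotypes, which the comparisons are about, as its error. The residuals of that fit were used only to set the scatter of the simulated arrays. No test was made, and log2 ratios, counts of genes at least 2-fold apart and medians of gene lists are given as descriptions of these arrays. A list's median is set beside its percentile among 10000 random lists of the same size, matched on mean level in 10 bins. Counts shared by a pair of comparisons are set beside the count expected of independent lists. Because both mutants were compared with the same wild-type arrays, the correlation of their differences is set beside that of 100 simulations of unchanged groups against a shared array. The procedure was tested on arrays simulated with the scatter seen here and 200 genes set 2, 3 or 4-fold apart. For the Clock mutant over wild type at CT14, 47.1%, 73.6% and 87.3% of these were found past 2-fold, as were 4.11% of unchanged genes. Bootstrap intervals (95%, 2000 draws) are over genes, which are not independent replicates.

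The comparisons, the 35 gene lists of pathways and cell types, a first set of alternatives and the rule for named genes were fixed before the data were examined. The rule names the clock genes and the targeted genes, the 10 largest differences in each direction above the floor on both arrays of a time contrast, the 10 largest in each direction by the smaller of the differences at the 2 times for a mutant against wild type, the 5 largest in each direction for the difference of a time effect between mutant and wild type, each of these among genes above the floor on all arrays compared, and up to 4 members with the largest ratio of each list described. Genes named only because they were shared between time contrasts were chosen after their values were seen.

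The alternatives fixed beforehand were the values as deposited, quantile normalization, lowess correction of each array against the mean (span 0.3), a floor at the 25th percentile, no filter on dim genes, a filter at the 75th percentile, the mean over all probe sets of a gene, and a threshold of 3-fold. Scaling, floor and filter taken without the Clock mutant CT02 array or without the Cry-deficient CT02 array, the use of only those probe sets whose names carry no extra letter, and the evening clock list without the targeted genes, were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.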

Results

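Liver RNA from male mice aged 8 to 10 weeks was measured on 6 one-colour Affymetrix mouse arrays, 1 array for each of 3 genotypes at 2 circadian times. Circadian time counts hours from the start of the subjective day, so that CT02 (2 h) falls early in the subjective day and CT14 (14 h) early in the subjective night. The genotypes were wild type (C57BL/6 background), Clock mutant and Cry-deficient. Clock encodes a transcription factor that pairs with the product of Arntl (Bmal1) to drive genes such as Per2 and Dbp, and the cryptochromes Cry1 and Cry2 repress that pair. The mean deposited intensity of the arrays was 2325 and 2382 in wild type at CT02 and CT14, 1637 and 2182 in the Clock mutant, and 2195 and 2486 in the Cry-deficient mice. Between 21.5% and 24.0% of the probe sets of an array lay at or below 0. After scaling, 4844 genes were kept, and 606 scaled units served as the floor below which no level was read. With 1 array per group no difference had a replicate check, so sizes are given without p-values, and the number of arrays limits the precision of every value. In arrays simulated with the scatter seen here, 42.3% of genes set 2-fold apart and 84.1% of genes set 4-fold apart were found past 2-fold in the wild-type time comparison, as were 4.60% of unchanged genes.

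The arrays differed in ways other than genotype and time. The ratio of the 3' to the 5' control probes of Actb, a sign of RNA length, was 0.84 and 0.93 in wild type, 2.68 and 1.15 in the Clock mutant at CT02 and CT14, and 1.70 and 0.86 in the Cry-deficient arrays. For Gapdh that ratio was 2.37 on the Cry-deficient CT02 array and between 0.56 and 0.72 on the others. For Pcx it was 19.7, 17.7 and 25.3 on the CT02 arrays and 3.96, 6.57 and 7.14 on the CT14 arrays of wild type, Clock mutant and Cry-deficient mice. The 5' control of Pcx read 788, 831 and 644 scaled units on those CT02 arrays, near the floor of 606, so their Pcx ratios are imprecise. The brightest 10% of the genes had a median log2 ratio of 0.24 in the Clock mutant over wild type at CT02 and -0.29 for CT14 over CT02 within the Clock mutant, both of which involve the dimmest array, one of -0.16 for CT14 over CT02 on the Cry-deficient arrays and one of 0.12 for the Cry-deficient CT02 array over wild type, and shifts of abundant gene groups in these comparisons stand beside those values.

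The targeted genes were read first. Cry1, on a probe set whose name marks a sequence family, stood at 1833 and 2723 in wild type at CT02 and CT14, at 3845 and 4718 on the Cry-deficient arrays, and at 1963 and 366 on the Clock mutant arrays, while its other probe sets lay under the floor on every array. Cry2 stood at 1215 and 2256 in wild type, 1185 and 1344 on the Cry-deficient arrays, and 1372 and 1886 on the Clock mutant arrays. Against wild type at CT02 and CT14, Cry1 had log2 ratios of 1.07 and 0.79 on the Cry-deficient arrays and Cry2 had -0.04 and -0.75. Where these probes lie relative to the deleted parts is not given in the sources used here, so they do not check the labels, and "Cry-labelled" is used below for the arrays labelled Cry-deficient, whose directions rest on the label alone. Clock stood at 2430 and 1552 in wild type and at 1640 and 2069 in the Clock mutant, a level that says nothing of a mutant allele.

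The first comparison asked which liver genes differed between early subjective night and early subjective day in wild type. Evening clock genes were higher at CT14. Per2, a repressor of the clock, was at least 6.69-fold higher (251 and 4058 scaled units), Bhlhe40, a repressor of clock-driven genes, was 5.01-fold higher, the deubiquitinase gene Usp2 4.64-fold (at least 1.81-fold on its second probe set) and the transcription factor gene Tef 2.50-fold. Of 11 evening clock genes kept, 4 were at least 2-fold higher and none was 2-fold lower, with a median log2 ratio of 0.83 (percentile 100 among 10000 random lists of like level). Arntl, which peaks in anti-phase to Per2, was 2.43-fold lower, and the 3 morning clock genes had a median of -0.65, which was -1.28 on probe sets with no letter in their names. Nr1d1 differed little (log2 ratio -0.45), and Dbp was near the floor (750 at CT14, below the floor at CT02).

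Some lipid genes and the stress genes also separated the wild-type arrays. Fasn, the fatty acid synthase gene, was 3.49-fold higher at CT14, Elovl6, a fatty acid elongase gene, 4.66-fold and Thrsp 2.84-fold, while Elovl3 was at least 3.14-fold lower. Of the 12 lipogenic genes 6 were higher and 6 lower, 4 and 1 of them at least 2-fold, with a median of 0.18. Lpin1, which acts in triglyceride synthesis, was 6.61-fold higher. Of 17 genes of the unfolded protein response 16 were higher, with a median of 0.64: Ddit3 was at least 5.10-fold, Creld2 4.48-fold and Dnajb9 2.14-fold higher. Of 14 heat shock genes 12 were higher, with a median of 0.59, led by Hspa1b (4.56-fold) and Hsph1 (2.61-fold). Gmppb (4.75-fold), Srm, the spermidine synthase gene (3.62-fold), and Rcan1 (3.45-fold) were among the other large differences. On the lower side stood Igfbp1, a fasting-responsive binding protein gene (at least 15.8-fold), Nr0b2, a repressor of bile acid synthesis (5.76-fold), Lpl (4.03-fold, with a second probe set at the floor on both arrays), the water channel gene Aqp8 (4.02-fold), Ltk (3.77-fold), Pla2g1b (3.75-fold), Inca1 (3.55-fold), Mtor (3.48-fold, with a second probe set at a log2 ratio of -0.72), Smagp (3.44-fold), Cldn1 (3.10-fold) and Traf2 (3.10-fold). The 16 cholesterol synthesis genes had a median of 0.07, with Lss 3.11-fold higher.

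In all, 120 genes were at least 2-fold higher and 101 lower at CT14 in wild type, 4.56% of the 4844 genes. That share is close to the 4.60% of unchanged genes that passed 2-fold in the simulation, so single genes in this count cannot be told from scatter by size alone. The simulated scatter was taken from all 6 arrays and includes real differences between genotypes in the effect of time.

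**Figure D1:**
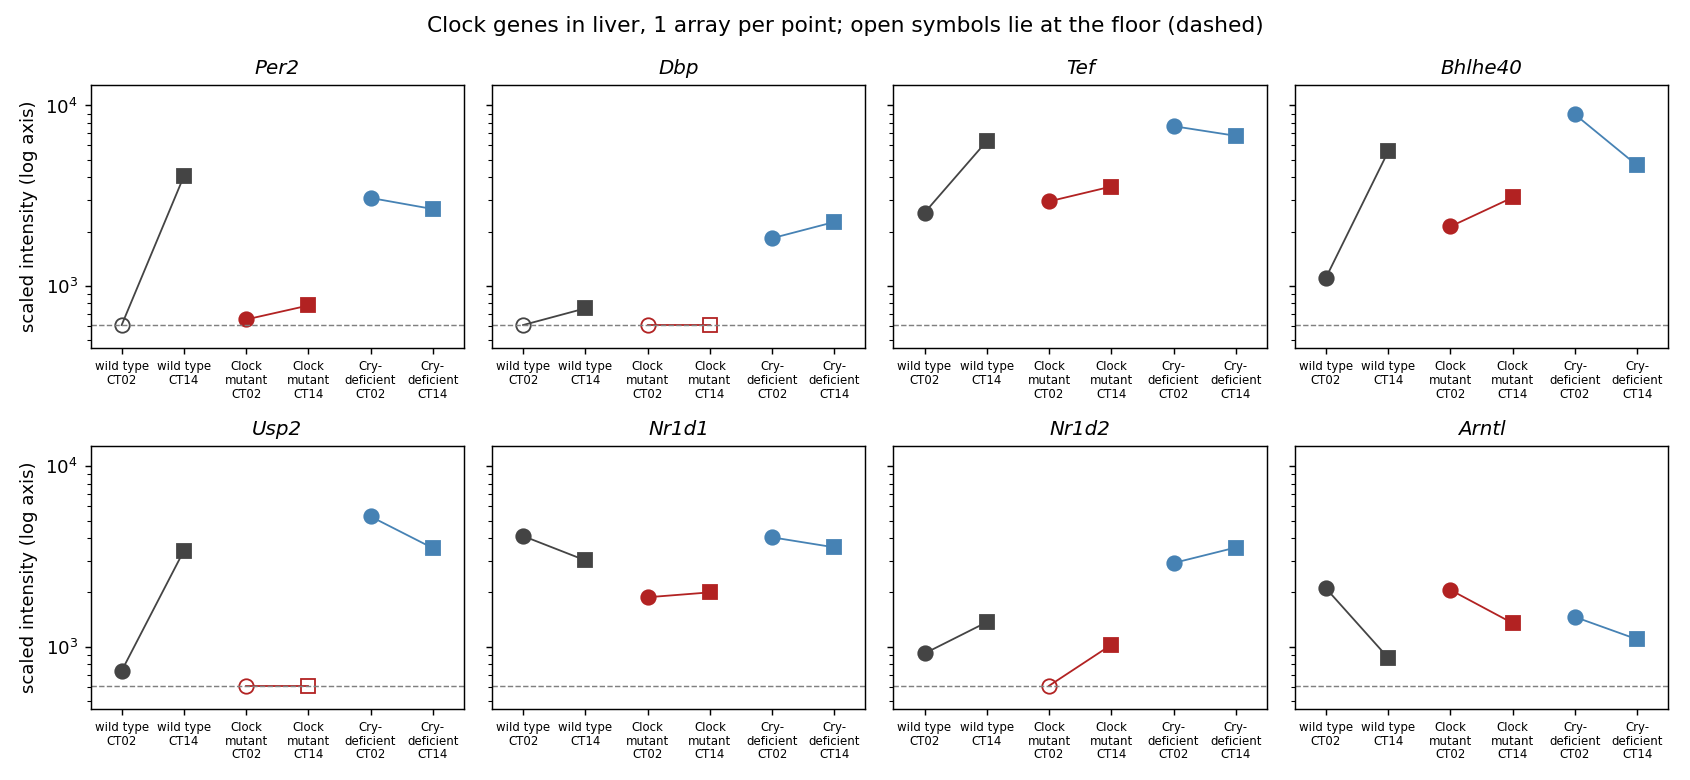
Scaled intensity (log axis) of 8 clock genes on each of the 6 arrays, 1 point per array, with circles for CT02, squares for CT14, a line joining the 2 times of a genotype and open symbols for values at the floor (dashed line). In wild type Per2 was at 4058 at CT14 and under the floor at CT02, on the Clock mutant arrays it was at 651 and 778, and on the Cry-labelled arrays at 3071 and 2665.

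The same time contrast within the Clock mutant asked which differences were present when Clock was mutated. Per2 (651 and 778), Tef (log2 ratio 0.27) and Bhlhe40 (0.53) differed little between the times, Dbp was under the floor at both, as was the brighter probe set of Usp2 (-1781 and -1779), whose second probe set read 625 and 416, Cry1 was at least 3.24-fold lower at CT14, and the 11 evening clock genes had a median of 0.09 (percentile 61.9). Lipogenic and sterol genes were lower at CT14: all 12 lipogenic genes were below their CT02 level, with a median of -0.59, among them Fasn (3.44-fold) and Elovl6 (3.23-fold), and 14 of 16 cholesterol synthesis genes were, with a median of -0.62, among them Fdps (3.21-fold), Lss (3.10-fold) and Dhcr7 (2.61-fold). The metallothionein gene Mt2 was 9.36-fold higher and Mt1 at least 22.0-fold higher. These contrasts share the dim CT02 array. The 9 hepatocyte markers had a median of -0.48 (-0.21 with quantile normalization, Alb 1.84-fold lower). All of them were bright except Apoa1, which read 609 and 146 scaled units in the Clock mutant at CT02 and CT14.

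Beyond these groups, Eif4b (8.24-fold, with a second probe set at a log2 ratio of 0.62), Socs2, a suppressor of growth hormone signalling (6.40-fold), Sult1a1 (5.89-fold), Wsb1 (5.80-fold), Myt1l (4.50-fold), Phlda1 (4.43-fold), Ceacam1 (4.21-fold), Col9a1 (4.03-fold) and Inpp4a (3.73-fold) were higher at CT14 in the Clock mutant. Mug-ps1 (6.08-fold), Itpk1 (5.89-fold), Serpina1e (5.36-fold), the repressor gene Bcl6 (5.06-fold), Tubb3 (4.99-fold), Gstm1 (4.43-fold, with a second probe set at -0.34), Ltk (3.86-fold), Serpina1c (3.80-fold), Upk2 (3.75-fold) and Tubb2a (3.74-fold) were lower. The 12 genes known to be higher in male liver had a median of -0.51, and the 3 neutrophil markers one of -0.81, which was -0.19 with no filter on dim genes. The count was 209 higher and 166 lower (375 genes). On the values as deposited, where the median of all genes lay at 0.46, it was 711 with 93.1% higher, against 55.7% after scaling.

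Within the Cry-labelled arrays the time contrast asked the same of mice labelled Cry-deficient. The evening clock genes had a median log2 ratio of 0.18 but a mean of -0.04, with no member 2-fold apart, and the median was -0.18 without the targeted genes Cry1 and Cry2 and -0.21 after lowess correction. Per2 stood at 3071 and 2665, Tef at 7680 and 6790, Usp2 at 5264 and 3514 (2124 and 2108 on its second probe set), and Bhlhe40 at 8924 and 4652 (log2 ratio -0.94). Cholesterol synthesis genes stood out: all 16 were higher at CT14, 11 of them at least 2-fold, with a median of 1.46 (percentile 100). Nsdhl was 7.86-fold, Hmgcs1 5.26-fold, Idi1 4.96-fold, Sqle 4.56-fold and Cyp51 4.56-fold higher. Igfbp1, lower at CT14 in wild type, was 6.36-fold higher.

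The liver at CT02 on the Cry-labelled arrays carried higher levels of acute-phase and macrophage genes. Of 23 acute-phase genes 22 were lower at CT14, 6 at least 2-fold, with a median of -0.30: Mt1 (at least 16.0-fold), Mt2 (9.36-fold), Orm2 (8.00-fold) and Saa2 (3.83-fold). Of 11 macrophage markers 9 were lower, with a median of -0.66, among them Marco (3.80-fold), Tyrobp (3.11-fold) and Cd5l (2.17-fold), whereas C1qa was 3.23-fold higher. The 6 B cell markers had a median of -0.46, and the 7 pericentral and the 7 periportal hepatocyte markers one of -0.40 each. The 30 genes of xenobiotic metabolism had a median of -0.21, which was -8.59e-05 on the values as deposited, where the median of all genes lay at 0.19, and the 17 unfolded protein response genes one of 0.25 (0.09 with no filter on dim genes), with Asns 3.65-fold higher. The transcription factor genes Onecut1 (5.25-fold) and Hnf4a (4.77-fold), P2rx7 (4.61-fold) and Serpina12 (4.43-fold) were higher, and Zbtb16 (6.23-fold), Rad51b (5.87-fold), Snrpb (5.73-fold), Sdc4 (5.14-fold), Nxf1 (4.23-fold), Cxcl13 (4.19-fold), Cnn1 (4.0-fold) and Bcl6 (3.96-fold) lower. The count was 171 higher and 98 lower (269 genes). On the values as deposited 81.9% of the counted genes were higher, against 63.6%.

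The 3 time contrasts had little in common over all genes. Across the 4844 genes, which are not independent replicates, Pearson's r was 0.02 between wild type and Clock mutant, 0.02 between wild type and Cry-labelled, and 0.03 between the mutants (Spearman's rho 0.00, 0.04 and 0.06). Over the 221 genes at least 2-fold apart in wild type, the slope of the mutant on the wild-type log2 ratio was 0.04 for the Clock mutant and -0.01 for the Cry-labelled arrays. Genes chosen by size on 1 pair of arrays shrink on any other pair, and the mirror slopes, of wild type on the mutant over genes chosen in the mutant, were 0.03 and 0.02. Genes at least 2-fold apart in both wild type and Clock mutant went the same way in 28 cases (8.64 for independent lists) and opposite ways in 22 (8.47). Of those going the same way 14 genes were higher at CT14 in both wild type and Clock mutant, where independent lists would share 5.18, among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Lpin1, Socs2, Fkbp5 and Nampt. Another 14 were lower in both (3.46 for independent lists), among them Igfbp1, Nr0b2 and Elovl3. Wild type and Cry-labelled arrays shared 12 higher genes (4.24 for independent lists), among them Cyp51, Lss and Mvd, and 2 lower genes (2.04), Arap3 and Cnn1, 14 in all, while 15 went opposite ways (5.99).

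Single genes had time ratios that lay far apart between genotypes. The genes ranked here were above the floor on all arrays compared, which leaves out larger differences that are lower bounds, such as those of Igfbp1 on the Cry-labelled arrays (at least 6.65) and of Wsb1 (at least 3.86) in the Clock mutant. Against wild type, the time ratio of the Clock mutant was lower for Elovl6 (log2 difference -3.91), Fasn (-3.59), Mug-ps1 (-3.43), Creld2 (-3.38) and Lss (-3.27) and higher for Eif4b (3.16), Fbxo21 (3.10), Ceacam1 (3.09), Mt2 (3.0) and Cyp4a14 (2.71). For the Cry-labelled arrays it was lower for Mt2 (-3.45), Hspa1b (-3.31), Lpin1 (-3.30), Bhlhe40 (-3.26) and Orm2 (-3.07) and higher for Hmgcs1 (3.22), Aqp8 (3.15), Nsdhl (3.12), Arsa (2.80) and Nr0b2 (2.65).

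The Clock mutant was then compared with wild type at each time, which asked how the level of liver genes differed in the mutant. At CT14 the evening clock genes were low: all 11 were below wild type, with a median of -0.83, and Per2 was 5.22-fold, Usp2 at least 5.62-fold (at least 1.81-fold on its second probe set) and Cry1 at least 4.49-fold lower. At CT02 the same list had a median of 0.00, with Nr1d1 2.18-fold lower. Stress genes were low at CT14 too. Of 17 unfolded protein response genes 15 were below wild type, 8 at least 2-fold, with a median of -0.84 (Creld2 6.53-fold, Manf 3.30-fold). All 14 heat shock genes were, with a median of -0.55 (Bag3 3.06-fold, Hspa1b 2.87-fold). In wild type most of these genes stood higher at CT14 than at CT02. At CT02 both medians lay above wild type after scaling. On the values as deposited, where the median of all genes lay at -0.52, they were -0.20 for the unfolded protein response and -0.13 for heat shock. At CT02 the cholesterol synthesis genes were high, 8 of 16 at least 2-fold, with a median of 1.0 (Lss 4.48-fold, Idi1 3.12-fold), as were the lipogenic genes, with a median of 0.65 (Thrsp 3.69-fold, Fasn 3.29-fold). At CT14 these medians were 0.26 and -0.28, with Elovl6 6.19-fold and Fasn 3.65-fold lower and Hmgcs1 3.40-fold higher.

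Some genes stood apart from wild type at both times, and those ranked here were above the floor on all arrays compared. Cyp2b10, a drug-metabolising cytochrome gene, was 12.0-fold higher in the Clock mutant at CT02 and 5.66-fold at CT14, Lpl 3.31-fold and 11.4-fold, Apcs 4.75-fold and 5.04-fold, Aqp8 2.81-fold and 6.47-fold, and Cyp2c39, of the xenobiotic list and under the floor in wild type at CT14, 6.82-fold and at least 19.1-fold. Higher too were U90926, Uros, Fhit, Hmgcs1, Ocel1 and Ccl9 between 2.64-fold and 4.31-fold. Glns-ps1 was lower by 8.18-fold and 5.37-fold, Tspan4 by 4.49-fold and 7.20-fold, Dynll2 by 6.35-fold and 6.69-fold, S100a13 by 4.05-fold and 5.29-fold, Stim1 by 5.58-fold and 3.17-fold and Srp9 by 5.41-fold and 3.0-fold. Xdh, Pex6, Lig3 and H1f2 were lower by 3.44-fold to 4.47-fold. Second probe sets of Dynll2 and S100a13 gave log2 ratios between -0.83 and -0.16, and that of Lig3 gave 0.19 at CT02 and -1.23 at CT14. Genes known to be higher in female liver had medians of 1.05 and 0.80 over 9 members, with Hao2 at least 3.68-fold and at least 3.27-fold higher, but 2 of the 9 were at least 2-fold lower at each time, the CT14 median was 0.06 after lowess correction, and both medians were 0.00 with no filter on dim genes. Stellate cell and fibroblast markers had medians of 0.46 and 0.52 (Sparc 2.53-fold higher at CT14), the former -0.10 on the values as deposited and both lower (0.16 and 0.22) with no filter on dim genes, and the hepatocyte markers one of -0.33 at CT14. The 58 oxidative phosphorylation genes had medians of 0.29 and 0.05, the former -0.26 on the values as deposited.

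At CT02 206 genes were at least 2-fold higher and 364 lower in the Clock mutant (570), and at CT14 200 were higher and 273 lower (473). On the values as deposited, where the median of all genes lay at -0.52, the CT02 count was 1032 with 5.62% higher, against 36.1%. Of these genes 56 were higher and 90 lower at both times (146), where independent lists would share 29.0, and 19 went opposite ways (26.6 for independent lists). The CT02 and CT14 differences, which share no array, correlated across genes with r = 0.38 (rho 0.34). In the simulation for CT14, 4.11% of unchanged genes passed 2-fold, against 9.76% observed. The simulated scatter was pooled over all 6 arrays. The Clock mutant time contrast had 7.74% of genes past 2-fold, against 4.56% in wild type, so 4.11% may be too low for a Clock mutant array.

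**Figure D2:**
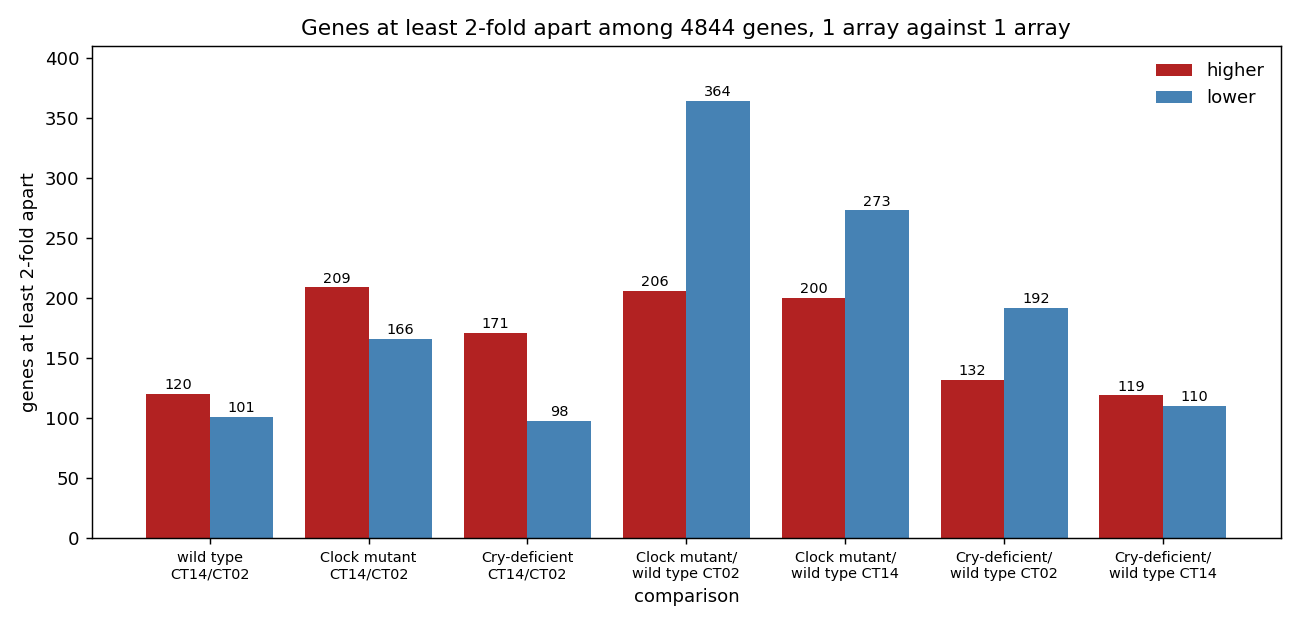
Number of genes (bars, from 0) at least 2-fold higher or lower among 4844 genes in each of the 7 comparisons, each of 1 array against 1 array. The Clock mutant differed from wild type in 570 genes at CT02 and 473 at CT14, and the wild-type times in 221.

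On the Cry-labelled arrays against wild type, the largest shift of a gene group at CT02 was that of the evening clock genes. Their median was 1.59 (percentile 100), with 7 of 11 at least 2-fold higher, the targeted gene Cry1 among them, and 1.60 with 6 of 9 without Cry1 and Cry2: Bhlhe40 8.03-fold, Usp2 7.18-fold (at least 3.50-fold on its second probe set), Per2 at least 5.07-fold, Nr1d2 3.17-fold and Tef 3.02-fold. At CT14 the median was 0.10, with Dbp 3.01-fold and Nr1d2 2.59-fold higher and Per2 at a log2 ratio of -0.61. The cholesterol synthesis genes lay the other way in time, with a median of 0.28 at CT02 and 1.51 at CT14 (2.31 with a filter at the 75th percentile), where 10 of 16 were at least 2-fold higher: Sqle 11.5-fold, Idi1 9.23-fold, Nsdhl 8.68-fold and Fdft1 5.23-fold. Stress genes were below the wild-type CT14 array, the one the Clock mutant was also compared with and on which these genes stood above wild-type CT02, with medians of -0.38 for the unfolded protein response (Ddit3 at least 5.10-fold lower) and -0.28 for heat shock (Hspa1b 8.21-fold lower).

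Cyp2b10 was 8.47-fold and 8.22-fold higher at CT02 and CT14, the glutathione transferase gene Gsta4 4.18-fold and 5.43-fold, Apoa4 2.65-fold and 3.79-fold, and Cpsf4 2.82-fold and 3.31-fold. Erdr1 and Tfap2a were higher too (2.62-fold to 3.34-fold), but their second probe sets had log2 ratios between -0.37 and -0.15, and without the Cry-labelled CT02 array in the scaling and filter another probe set stood for Tfap2a, with -0.15 at CT14. Serpina12 was 5.96-fold and 2.96-fold lower, Gstm6 2.23-fold and 5.66-fold, H1f2 2.23-fold and 4.90-fold and Cd59a 3.75-fold and 3.49-fold. Prpsap1, Chka, Fabp2, Adam5, Ccnf and Tbc1d15 were lower by 2.03-fold to 3.80-fold, with a second probe set of Tbc1d15 at 0.60 and -0.04. At CT02, where the brightest 10% of the genes stood at 0.12, the 30 genes of xenobiotic metabolism had a median of 0.25, the macrophage markers one of 0.52 (Marco at least 4.67-fold higher, C1qa 3.17-fold lower), the periportal markers one of 0.31 (Ass1 4.41-fold higher) and the acute-phase genes one of 0.19, with Mt2 7.27-fold higher. At CT14 the 7 endothelial markers had a median of 0.58 and the 6 pancreas markers one of 0.83, which was 0.00 with no filter on dim genes. The wild-type CT14 array was itself low for the endothelial markers, all 7 of which lay below their wild-type CT02 level. The female-biased genes had medians of 0.38 and 0.55, both 0.00 with no filter on dim genes.

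The counts were 132 higher and 192 lower at CT02 (324), and 119 higher and 110 lower at CT14 (229). At CT02 40.7% of the counted genes were higher, against 28.6% on the values as deposited and 52.3% after lowess correction. Of these genes 23 were higher and 23 lower at both times (46), where independent lists would share 7.60, 12 went opposite ways (7.71 for independent lists), and the differences at the 2 times correlated with r = 0.16 (rho 0.15).

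**Figure D3:**
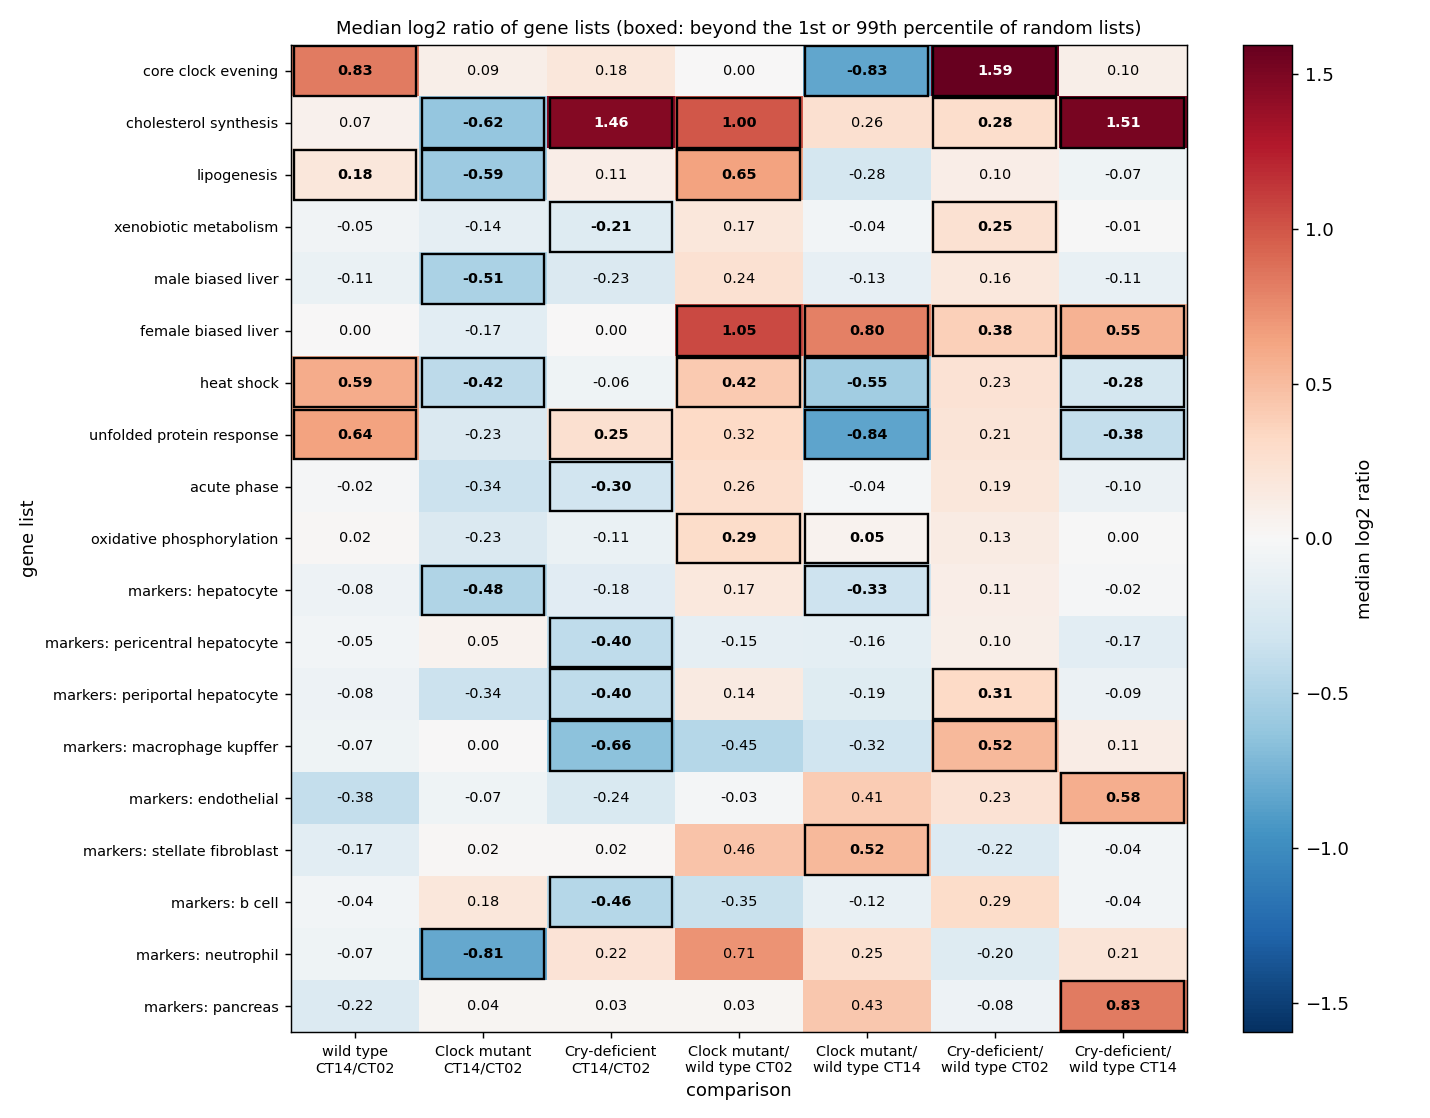
Median log2 ratio of 19 gene lists (rows) in the 7 comparisons (columns), coloured by value, with a box where the median lay at or beyond the 1st or 99th percentile of 10000 random lists of like level. The evening clock list was at 0.83 in the wild-type time contrast, -0.83 in the Clock mutant over wild type at CT14 and 1.59 in the Cry-labelled array over wild type at CT02, and cholesterol synthesis was at 1.51 in the Cry-labelled array at CT14.

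Last, the differences of the 2 mutants from wild type were set against each other. Taken at different times, so that no array was shared, they correlated across genes with r = -0.04 (Clock mutant CT02 with Cry-labelled CT14) and -0.02 (Clock mutant CT14 with Cry-labelled CT02). Taken at the same time, against the same wild-type array, r was 0.22 at CT02 and 0.35 at CT14, with covariances of 0.08 and 0.10. Unchanged groups simulated against a shared array gave a mean r of 0.50 and a covariance of 0.12, which the observed values did not exceed. The simulated scatter includes real differences between genotypes in the effect of time, which raises that covariance. Whether the shared array alone accounts for the observed values can therefore not be decided here. Cyp2b10 and Hmgcs1 were examples of genes above wild type at CT14 in both mutants, and H1f2 was at least 2-fold lower in both at both times.

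Where a kept gene had a second probe set above the floor (666 genes), the log2 ratios of the pair correlated with r between 0.17 and 0.39 over the 7 comparisons. Among genes at least 2-fold apart, 50% to 79.6% of second probe sets had the same direction and 14.6% to 33.3% were 2-fold apart the same way. Of all second probe sets, 2.70% to 7.73% were 2-fold apart that way. The 50% was that of the Cry-labelled array over wild type at CT02, where 23 second probe sets went the same way and 20 the opposite way. Directions of the pairs thus hardly agreed there. Of the 35 gene lists 33 had at least 3 kept genes. Of their 231 medians 24 lay at or above the 99th percentile of their random lists and 18 at or below the 1st. Independent lists of independently drawn genes would give 4.62 in all. That number is not a chance level for these data, because lists share genes, comparisons share arrays and variation between mice does not enter it.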

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

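Of the tests in this part, those of the ribosomal RNA signal and of the scaling of the clock list were written before their results were seen, the clock list without Cry1 and Cry2 was added after, and the tests of macrophage RNA, including how markers under the floor were read, and of the scaling behind Mt1 and Mt2 were chosen after, in place of tests on the Clock mutant CT14 array whose values had been seen, while tests of the Clock mutant CT02 array alone and of a wrong genotype label, also chosen after, were left out because the patterns themselves fix their outcome.

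Of the genes named for the size of their time ratio or of its difference from wild type, 14 were at least 2-fold apart between the times in opposite directions in 2 genotypes, and with 1 array per group none of these differences was tested. Igfbp1 was lower at CT14 in wild type and higher on the Cry-labelled arrays, with a log2 difference of at least 6.65, since wild type lay at the floor at CT14. Mt2 was higher at CT14 in the Clock mutant and lower on the Cry-labelled arrays (6.45), as was Zbtb16 (at least 4.02). Elovl6 (3.91), Gmppb (at least 3.78), Fasn (3.59), Creld2 (3.38) and Lss (3.27) were higher at CT14 in wild type and lower in the Clock mutant. Wsb1 (at least 3.86), Fbxo21 (3.10), Ceacam1 (3.09) and Cyp4a14 (2.71) were lower in wild type and higher in the Clock mutant. Hspa1b (3.31) was higher in wild type and lower on the Cry-labelled arrays, and Aqp8 (3.15) was lower in wild type and higher there. The cholesterol synthesis genes as a group were higher at CT14 on the Cry-labelled arrays and lower in the Clock mutant, with medians 2.08 apart.

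The 18S ribosomal RNA control probes, which no comparison uses, read 4.99 times the wild-type mean on the Clock mutant CT02 array, 9.89 times on the Clock mutant CT14 array and 3.27 times on the Cry-labelled CT14 array, above both wild-type arrays, and 0.41 times on the Cry-labelled CT02 array, below both.

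The Clock mutant differed from wild type in the same genes and direction at both times more often than independent lists would, in 146 genes against 29.0, in contrasts that share no array. If the amount of ribosomal RNA in the sample were behind it, these genes would also separate the Cry-labelled arrays. Mean 18S signals there were 671 at CT02 and 5365 at CT14 (7.99-fold), and the median signed log2 ratio of these genes was 0.00 (bootstrap interval -0.03 to 0.05). The Clock mutant over wild type differed 5.48-fold and 9.07-fold at CT02 and CT14, with signals of 8189 and 16242 in the mutant. The 7.99-fold rests partly on controls under the floor (124 and 494 on the Cry-labelled CT02 array), and the Cry-labelled arrays also differ in time. The test therefore covers only lower 18S signals and leaves ribosomal RNA at the Clock mutant levels open. An effect of the Clock mutation, the strain background of the mutant mice, which the labels do not state, and a difference in how the arrays of a genotype were handled stay open, since no array separates them. The mutation is therefore a candidate explanation and was not tested against these.

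The evening clock genes were high on the Cry-labelled CT02 array, with a median of 1.59 against wild type (1.60 without Cry1 and Cry2), and close to wild type at CT14 (0.10). Scaling does not account for it, as the log2 offsets of the wild-type and Cry-labelled CT02 arrays (0.12 and -0.004) were small beside that median. The CT02 median against wild type was between 1.47 and 1.62 under the 3 other scalings, a result that such offsets made nearly certain. A liver of another genotype or time than its label stays open, and the probes of Cry1 and Cry2 did not check the genotype. The loss of cryptochromes that the label names stays open as well and was not tested.

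Mt1 and Mt2 were high on the Cry-labelled CT02 array, with log2 ratios to wild type of at least 4.0 and of 2.86. Scaling does not account for it, as the log2 offsets of the wild-type and Cry-labelled CT02 arrays (0.12 and -0.004) were small beside these ratios. The lower of the pair stayed at 2.74 or more under the 3 other scalings, which with such offsets could hardly have come out otherwise. Extra RNA of the macrophages that the liver already holds would raise their own genes at least as much, yet the 11 markers had a median of 0.52 (bootstrap interval 0.43 to 1.29) and the highest of the 9 measured above the floor on both arrays, Tyrobp, had 1.29. Marco had at least 2.22, but markers under the floor in wild type already lay above the median, which does not depend on their true ratios. Macrophages in another state, a state of the single mouse or pool behind the array, RNA length, genotype and time stay open and were not tested. The Gapdh 3' to 5' ratio of this array was 2.37, against 0.56 to 0.72 on the others. Mt1 and Mt2 stood at 9698 and 9174 scaled units here and at 13356 and 14582 on the Clock mutant CT14 array. High levels were thus not particular to this array.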

How the results depend on the processing

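The signal over background limits what can be read of dim genes. The 3 settings without an array or with restricted probe names, the evening clock list without Cry1 and Cry2, and the distances from the wild-type midpoint, were chosen after seeing the data. The 7 correlations moved by less than 0.1 in all 62 recomputed values, and both slopes in all 18. Most of these values are themselves smaller than 0.1, so that limit could hardly be passed. Over the other settings the Clock mutant slope ran from 0.01 to 0.13, and r between the wild-type and Clock mutant time contrasts from 0.01 to 0.07. Of 93 recomputed counts 71 stayed within 1.5 times the reported count. Of 2115 list medians 2082, and of 9937 ratios of single genes 9742, moved by less than 1.5-fold without a change of sign of a median of at least 0.2 or a gene ratio of at least 1. The 1.5-fold limit is wide beside many list medians. In the Clock mutant time contrast the lipogenic median of -0.59 reached -0.09 and the cholesterol synthesis median of -0.62 reached -0.12, both within the limit. The values as deposited differ by 1 factor per array, too small here to move a single gene's ratio past the limit. All 1063 ratios stayed within it there by construction. The filters on dim genes do not alter a single gene's ratio, and so test nothing there. The causes of the other shifts were not tested, except where the construction shows them. With a threshold of 3-fold, which counts fewer genes by construction, the time contrasts gave 47 genes in wild type, 80 in the Clock mutant and 74 in the Cry-labelled arrays; the Clock mutant against wild type gave 151 at CT02, 118 at CT14 and 31 at both, and the Cry-labelled arrays 99, 60 and 9. With a filter at the 75th percentile, which leaves fewer genes, these counts were 73, 122 and 86, then 200, 181 and 55, then 111, 63 and 18. With a floor at the 25th percentile, which lets dimmer values count, the Clock mutant time contrast gave 579 genes and the Cry-labelled arrays 81 at both times. On the values as deposited, the median of all genes lay at -0.52 for the Clock mutant over wild type at CT02, 0.46 for its time contrast, 0.19 for the Cry-labelled time contrast and -0.11 for the Cry-labelled array over wild type at CT02, and 13.2% of the 190 genes at both times in the Clock mutant were higher, against 38.4%. The Clock mutant counts were then 1032 at CT02 and 711 in the time contrast. That same shift turned list medians of the Clock mutant. At CT02 against wild type they were -0.25 for acute phase, -0.12 for cell cycle, -0.35 for glycolysis, -0.13 for heat shock, -0.33 for iron and heme, -0.32 for male-biased genes, -0.0114 for adipose markers, -0.10 for stellate markers, -0.26 for oxidative phosphorylation and -0.20 for the unfolded protein response. In its time contrast they were 0.16 for acute phase, 0.30 for bile acid genes, 0.10 for gluconeogenesis, 0.15 for glycolysis, 0.0753 for heat shock, 0.23 for iron and heme, 0.0365 for periportal markers, 0.25 for oxidative phosphorylation, 0.0585 for ribosomal proteins and 0.16 for the unfolded protein response. All of these lay above -0.52 at CT02 and below 0.46 in the time contrast, the medians of all genes there. Deposited and scaled values differ by 1 factor per array, so directions relative to those medians stay almost by construction, which tests nothing. Under other settings, glycolysis in the Clock mutant at CT02 was at -0.00769 with quantile normalization and iron and heme at -0.000254 with probe names without letters. The latter setting also put the morning clock genes at -0.0403 on the Cry-labelled arrays and -1.28 in wild type, pancreas markers at 0.63 in the Clock mutant at CT02, Atp5d at 0.22 and Ighm at -0.0593 in the Clock mutant at CT14. With no filter, the female-biased medians in the Clock mutant were 0.00 at both times, the muscle markers at CT02 and the pancreas markers at CT14 in the Cry-labelled arrays 0.00, the neutrophil markers in the Clock mutant time contrast -0.19, and the midpoint distance of wild-type lower genes on the Cry-labelled CT02 array -0.0102. Lowess correction put the female-biased genes in the Clock mutant at CT14 at 0.0617. The filter at the 75th percentile put cholesterol synthesis in the Cry-labelled CT14 array at 2.31 and stellate markers at CT02 at 0.16. Without the Cry-labelled CT02 array Tfap2a was at -0.15 at CT14. The labels number no replicates, and a fit with time as a block was not used to test genes.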

Other observations

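The genes named below for being shared by the mutants and the distances from the wild-type midpoint were chosen after their values were seen. In the time contrasts of the 2 mutants, which share no array, 25 genes were higher at CT14 in both (7.38 for independent lists) and 13 lower (3.36), while 23 went opposite ways (10.1). Among the higher ones were Socs2 and Cish, which encode suppressors of cytokine and growth hormone signalling, the transcription factor gene Onecut1, the kinase gene Pim3 and Gadd45g, and among the lower ones the repressor gene Bcl6. Cish had log2 ratios of 0.53 in wild type, 1.18 in the Clock mutant and 1.40 on the Cry-labelled arrays, Socs2 1.22, 2.68 and 1.27, Onecut1 1.27, 1.39 and 2.39, and Gadd45g 0.37, 1.23 and 1.96. Pim3 had 0.36 in wild type, at least 1.48 in the Clock mutant and at least 2.60 on the Cry-labelled arrays, and Bcl6 -0.46, -2.34 and -1.99.

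Further gene groups in wild type and the mutants had smaller shifts. All 7 endothelial markers were lower at CT14 in wild type, with a median log2 ratio of -0.38 (Kdr 1.75-fold, Eng 1.62-fold). The immediate-early genes, which respond within minutes to stimulation, had a median of -0.34 in the Cry-labelled array against wild type at CT02, with 5 of the 8 kept genes lower and none 2-fold apart, and the median was 0.00 with no filter on dim genes. The interferon-response genes had a median of 0.22 on the Cry-labelled array against wild type at CT14, with Igtp 2.45-fold higher. In that comparison the pancreas markers were led by Pla2g1b (3.57-fold) and Clps (2.61-fold). They stood at 755 and 901 scaled units in wild type and 2697 and 2349 on the Cry-labelled array. On the wild-type CT02 array Pla2g1b stood at 2831, above the Cry-labelled level, and Clps at 995. With no filter on dim genes the median of the group was 0.00.

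Genes at least 2-fold apart in wild type were also placed relative to the midpoint of their 2 wild-type levels. The 101 genes lower at CT14 in wild type lay 0.19 above the midpoint (median log2) on the Cry-labelled CT14 array, with a bootstrap interval over genes of 0.08 to 0.34. The 120 genes higher at CT14 lay 0.22 above it on that array, with an interval of -0.05 to 0.29. On the Cry-labelled CT02 array the medians were 0.26 (-0.20 to 0.41) for the genes lower at CT14 and 0.07 (-0.10 to 0.17) for those higher. On the Clock mutant arrays the medians were -0.16 and -0.09 for the genes higher at CT14 and 0.09 and 0.05 for those lower, at CT02 and CT14, and each interval spanned 0.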
